A study of Zea mays with 10 samples.

How the data were processed

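RNA-seq libraries came from 6 separate pools, each of more than 10 ears of 1 mm, from fea4 mutants (3 pools) and fea4/+ siblings (3 pools), and groups and replicate numbers were taken from the sample titles. Per the labels' protocols, the plants segregated in families grown in the field, mRNA was selected with oligo-dT and libraries were made with a ScriptSeq kit. The kit marks strand, but whether counting used strand is not given in the sources used here, so a gene and an overlapping antisense gene could not be told apart. The sequencing lane or batch of each library is not given in the sources used here, so a batch that runs along with genotype stays possible. ChIP-seq libraries came from tassel primordia of plants carrying YFP-FEA4, precipitated with an anti-GFP antibody, with 2 ChIP and 2 input replicates, and per the labels each input belongs to the peak list of the same number. The inputs entered the work only through the authors' peak lists.

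The expression values are expected counts, which the authors deposited as raw fragments per gene and of which 11.4% to 14.1% per library were not whole numbers. The authors deposited FPKM values of the same genes, normalised for gene length and library total, which were used for an alternative test. The authors also deposited a log2 fold change and an adjusted p-value per gene, per the file headers from DESeq. The submitters' processing notes name CASAVA, TopHat2 2.0.9, Cufflinks 2.0.2 and DESeq 1.14.0 for these libraries, without their roles. The genome build and annotation behind the expression table are not given in the sources used here. The peak lists hold the authors' peak score and the signal height at each summit as deposited, and the submitters' processing notes name Bowtie 0.12.7 and MACS 1.4.0rc2. Peaks were called per replicate, the lowest score in the deposited lists was 50.01, and chromosome names in the files carry the build AGPv2.

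Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, filterByExpr, robust, genotype as the only term, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. TMM factors were 0.964 to 1.034, and the median log2 fold change of all genes lay within 0.01 of 0 in this fit and in those with RLE size factors, without the filter and with the replicate block. Levels are CPM, fragments scaled to library size with TMM factors. Fold changes are mutant over sibling. Library totals ranged from 8168955 to 28323324 fragments, and the common biological coefficient of variation was 20%. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 9.48 to 17.07, Pearson's r across genes 0.9739 to 0.987), so each was counted as its own sample. Counting intervals and floors of 3 counts cover counting error only, since fragments without molecular identifiers are not independent molecules.

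On simulated counts for 20244 genes with the libraries' own means and sizes, this test recovered 23.9% of 67 genes changed by 0.5 on the log2 scale, 44.8% of 67 changed by 1 and 77.3% of 66 changed by 2, with the right sign in each recovered gene, and 3 of its 100 calls were unchanged genes. In a simulation of the list tests, a list shifted by 0.4 was called and 0 of 20 unshifted lists were called by camera. Genes were simulated as independent of each other, so this did not check the preset correlation. In the real data the estimated correlation was 0.128 in the inflorescence list and 0.2 in the ribosome list. It was 0.019 in the auxin list and −0.008 in the homeobox list. In a simulation of the peak overlap, 300 of 300 planted overlaps were found, with 3 others.

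Gene names came only from a reference name table for the assembly Zm-B73-REFERENCE-NAM-5.0, whose coordinates were not used, apart from the order of neighbouring genes. Of 39636 gene IDs in the expression table, 18255 (46.1%) matched exactly 1 entry, and 2515 had a gene name. Of the 512 changed genes 87 had one, so the 425 others could enter no list or name. The 15 lists and the rule for named genes were fixed before the data were examined. The table gives no descriptions, so family words in the lists were written as the symbol stems that maize genes use. That was done after the names and the total number of changed genes had been seen, and before any list was tested. The symbols phb1 to phb3 were left out because they also name prohibitins. Haemoglobin genes (Hb, Hb2) and a second GT1 gene, which share symbols with list members, were taken out after their values had been seen, and the tests were repeated with them kept in. hdz10, a homeodomain gene that the stems missed, was added to the homeobox list in a further repeat. The stems also took in rrb1 and rrb2 (retinoblastoma-related) as cytokinin genes and grf1 and grf2 (GF14) as lateral organ genes, and a last repeat left these out. Other members may have been taken in by a shared symbol in the same way. The stems did not take in m21, whose symbol has the same form as the MADS-box members m24 and m31, and no repeat was run with it.

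The lists were meristem size and homeobox regulators, inflorescence branching and meristem determinacy, MADS-box floral genes, lateral organ identity and boundary, auxin, gibberellin, cytokinin, brassinosteroid with abscisic acid, ethylene and jasmonate, bZIP factors and glutaredoxins, cell cycle and DNA replication, ribosome and translation, photosynthesis, vascular and cell wall, heat shock and stress, and pollen, tapetum and seed. The 13 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided, Benjamini-Hochberg over the 13) and again with an estimated correlation. The named genes were FEA4, the 12 largest increases and 12 largest decreases among changed genes with separated libraries, a gene name and at least 1 CPM in the higher genotype, up to 4 changed members of each list with the smallest adjusted p, and kn1, zag1, td1, fea2 and wus1. This gave 55 genes, of which 54 were tested and 49 passed. ocl3 was named outside the rule, after its values were seen.

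Peak lists were compared by overlap of at least 1 bp with bedtools 2.31.1, with chance from 1000 seeded shuffles of replicate 2 peaks within chromosomes. Alternatives were a reciprocal overlap of 0.5, summits within 150 bp, a score of at least 100, equal numbers of best-scoring peaks and, added after the data were seen, local shifts of 20 to 100 kb. Alternatives for the expression tests were RLE size factors, no filter on low counts, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma on log2(FPKM + 1) for genes with a mean FPKM of at least 1 in a genotype, the authors' calls, a threshold of 0.1 and a minimum absolute log2 fold change of 1.

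Genes near FEA4 peaks, the overlap of such genes with the changed genes and the naming of genes by peak score were planned and not analysed here, because they need gene positions in AGPv2, which were not used here. Simulations and intervals used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9. The result for a single named gene is not reported here.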

Results

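The series measured gene expression and transcription factor binding in young maize inflorescences. FEA4 (FASCIATED EAR4) is a bZIP transcription factor named in the series title as a regulator of shoot meristem size, and plants that lack it form broad, flattened ears. RNA-seq was carried out on ear primordia of 1 mm, as 3 pools from homozygous fea4 mutants and 3 pools from heterozygous fea4/+ siblings, which look normal and are called siblings here. The pools held 15970835, 17474799 and 20956775 fragments in sibling replicates 1 to 3 and 19846056, 8168955 and 28323324 fragments in mutant replicates 1 to 3. Mutant replicate 2 was the shallowest library, where a normalised level of 1 CPM stood for 8.2 fragments. ChIP-seq was carried out on tassel primordia of 2 to 5 mm that carried a YFP-tagged FEA4, as 2 immunoprecipitated libraries with 2 input libraries, and gave 1 list of peaks per replicate.

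The first comparison asked which transcripts changed in ears that lacked FEA4. Several regulators of inflorescence branching and meristem determinacy were lower in the mutant ears, among them ra1, ra3, BA1 and bd1. Some auxin response and transport genes were lower too, as were some homeobox genes, 4 of them in the epidermal HD-ZIP IV class. Levels come from pools of whole ears, so a lower level per cell and fewer expressing cells could not be told apart. Some ribosomal protein genes were slightly higher. These 4 lists passed camera with a preset correlation between genes of 0.01, and 0 of the 13 tested lists passed with an estimated one. Among the 87 changed genes with a gene name, the largest increases included bx1 and bx2 of benzoxazinoid synthesis, lipoxygenase genes, pdk1 and the fermentation genes adh1 and pdc3. Of 20618 genes tested, 512 changed at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 289 higher and 223 lower in the mutant. The changes were mostly small, with a median absolute log2 fold change of 0.63, and 117 of the 512 changed by at least 1 on the log2 scale (55 higher, 62 lower). The 3 mutant values lay all above or all below the 3 sibling values for 20.8% of all tested genes, against 10% by chance, and for 505 of the 512 genes, which a test on these same libraries selects for. The count depended on the libraries used: it fell to 182, 260, 229 and 156 genes without sibling replicate 1, sibling replicate 2, mutant replicate 1 or mutant replicate 3, and rose to 811 without the shallow mutant replicate 2. It was 922 without the filter on low counts, 893 by DESeq2 and 186 by limma on log2(FPKM + 1).

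The FEA4 transcript itself (GRMZM2G133331) was present in all 6 libraries, with 102, 101 and 142 fragments in the siblings and 156, 44 and 156 in the mutants. Its level was 6.19 CPM ± 0.584 in siblings and 6.39 CPM ± 1.46 in mutants (SD, n = 3 each), and its log2 fold change was 0.05 ± 0.29 (SE, edgeR adjusted p = 0.959). The reference allele came from chemical mutagenesis, so transcript abundance did not check the genotype labels. Without sibling replicate 2 or mutant replicate 1 the log2 fold change was −0.02 or −0.15. Of the genes that set meristem size in maize, kn1, the homeobox gene that marks the meristem, had 872 CPM ± 73.7 in siblings and 870 CPM ± 156 in mutants (SD, n = 3 each; edgeR adjusted p = 0.992). The receptor-like genes fea2 and td1 had log2 fold changes of −0.25 ± 0.13 and −0.61 ± 0.21 (SE; edgeR adjusted p = 0.36 and 0.132). The stem cell regulator wus1 was near the detection limit, with 1.31 CPM ± 0.418 and 1.27 CPM ± 0.763 (SD, n = 3 each; edgeR adjusted p = 0.999), so a moderate change in it was not detectable at this depth. The floral gene zag1 was listed at 0 in all 6 libraries, as were 12154 gene models in total, and was not tested.

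**Figure D1:**
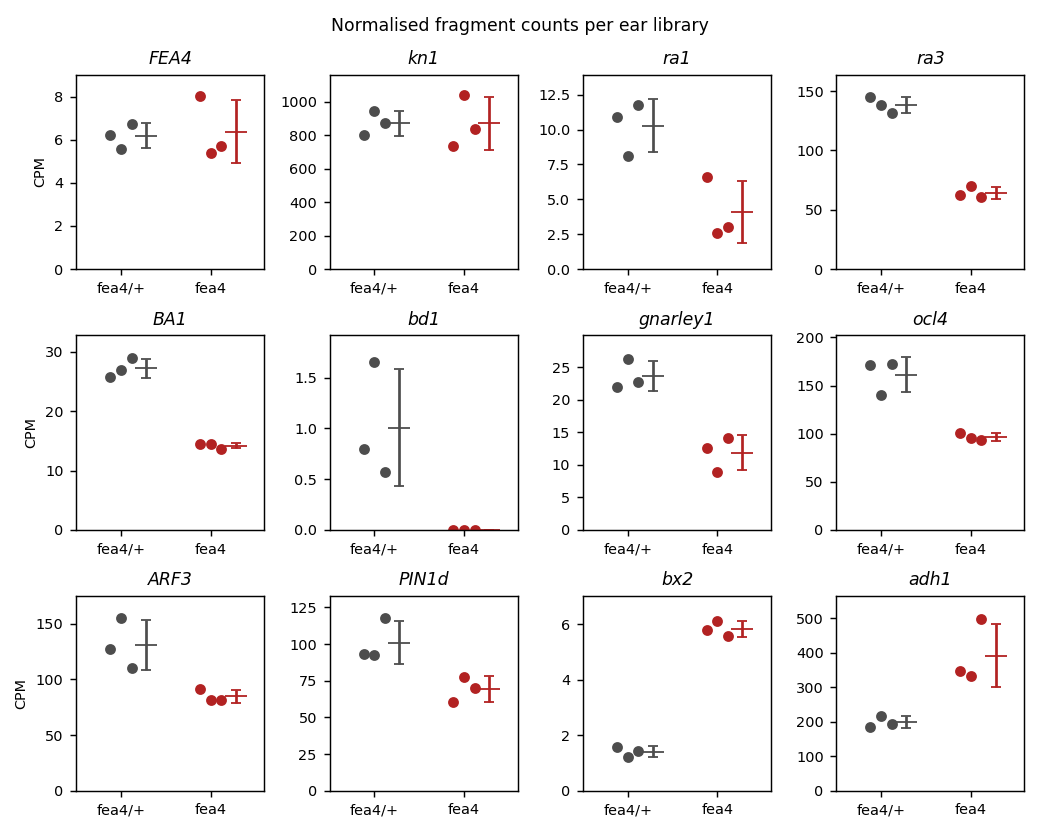
Normalised fragment counts (CPM, vertical axis) of named genes in the 3 fea4/+ sibling libraries (grey points) and the 3 fea4 mutant libraries (red points), with the mean and SD beside each group (n = 3). FEA4 and kn1 overlap between genotypes, bd1 had 55 fragments in the siblings and 0 in the mutants, and ra3 lay near 138 CPM in siblings and near 64.2 CPM in mutants.

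The list of inflorescence branching and meristem determinacy was lower by camera (adjusted p = 3.72e-07), but not past the threshold with an estimated correlation between genes in place of the preset 0.01 (adjusted p = 0.117). Of the 16 tested members, 4 were lower and 0 higher, 12 did not pass, and 6 were lower when adjusted over the list alone (0 higher and 8 lower at an unadjusted edgeR threshold of 0.05, 0 and 4 by DESeq2). The clearest was ra3, a trehalose-6-phosphate phosphatase that limits branching of the ear, with 138 CPM ± 6.42 in siblings and 64.2 CPM ± 4.88 in mutants (SD, n = 3 each), a log2 fold change of −1.11 ± 0.10 (SE, edgeR adjusted p = 2.32e-05). BA1, a bHLH factor needed to start axillary meristems, had a log2 fold change of −0.95 ± 0.17 (SE, edgeR adjusted p = 0.00399), and ra1, a zinc finger factor that makes spikelet pair meristems determinate, had −1.31 ± 0.34 (SE, edgeR adjusted p = 0.0451). The spikelet meristem gene bd1 had 55 fragments over the 3 sibling libraries and 0 over the 3 mutant libraries, at least 18.1-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 0.032). DESeq2 gave no adjusted p for bd1, so the 4 lower members by DESeq2 were not the same 4. The median log2 fold change of the list was −0.44, also with bd1 at its bound. The calls of ra3 and BA1 held whichever library was left out (highest edgeR adjusted p = 0.000454 and 0.0348). Those of ra1 and bd1 were lost on leaving out any of 5 of the 6 libraries, with edgeR adjusted p up to 0.243 and 0.201, both without mutant replicate 3.

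Of 42 tested auxin genes, 4 were lower, 0 higher and 38 not past the threshold, with 7 lower when adjusted over the list alone (0 higher and 18 lower unadjusted, 0 and 6 by DESeq2). The auxin response factors ARF30 and ARF3 had log2 fold changes of −0.95 ± 0.16 and −0.63 ± 0.12 (SE, edgeR adjusted p = 0.0033 and 0.00653). The efflux carrier gene PIN1d had −0.55 ± 0.12 and the import carrier gene aic1 −0.56 ± 0.14 (SE, edgeR adjusted p = 0.0187 and 0.0403). Camera gave an adjusted p of 2.51e-06 with a median of −0.25, and an adjusted p of 0.0718 with an estimated correlation. ARF30 kept its call whichever library was left out, whereas aic1 lost it in each of the 6 cases, with edgeR adjusted p of 0.0526 to 0.172.

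In the list of meristem size and homeobox regulators, 5 of 47 tested members were lower, 0 higher and 42 not past the threshold, with 12 lower and 1 higher when adjusted over the list alone (2 higher and 18 lower unadjusted, 1 and 6 by DESeq2). The members past the threshold were mostly not meristem size genes: ocl4 (−0.74 ± 0.10, edgeR adjusted p = 0.000893), ocl3 (−0.78 ± 0.20, 0.0399), HDZIV6_OCL6 (−0.80 ± 0.15, 0.00675) and HDZIV8_OCL8 (−0.57 ± 0.13, 0.0275) are HD-ZIP IV genes, a class active in the outer cell layer, each given as log2 fold change ± SE. The 3 other tested genes of that class, ocl1, ocl5 and HDZIV14_OCL14, had −0.24, −0.36 and −0.83 and did not pass (edgeR adjusted p = 0.395, 0.163 and 0.24). The class was not tested as a list. The last member past the threshold, gnarley1, is a knotted1-like gene with a log2 fold change of −0.97 ± 0.20 (SE, edgeR adjusted p = 0.0121). Camera gave an adjusted p of 0.000214 with a median of −0.23, and an adjusted p of 0.0718 with an estimated correlation. hdz10, a homeodomain-leucine zipper gene outside the list, was higher, with a log2 fold change of 1.79 ± 0.32 (SE, edgeR adjusted p = 0.00488). With hdz10 added to the list, camera gave an adjusted p of 0.00136.

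Of 47 tested ribosome and translation genes, 6 were higher, 0 lower and 41 not past the threshold, with 15 higher when adjusted over the list alone (20 higher and 0 lower unadjusted, 12 and 0 by DESeq2). The ribosomal protein gene RPL19 and the acidic protein genes arpp2b and arpp2a-2 had log2 fold changes of 0.49 ± 0.10, 0.58 ± 0.10 and 0.46 ± 0.09 (SE; edgeR adjusted p = 0.0104, 0.00307 and 0.011). The median over the list was 0.18, and camera gave an adjusted p of 7.99e-09, and an adjusted p of 0.257 with an estimated correlation. A trend of the test statistic with gene length and expression level was then removed. The median moved to 0.11 and the adjusted p by limma's cameraPR, with the preset correlation of 0.01, from 2.82e-10 to 0.00175. Ribosomal protein genes have close paralogs, so the values of single members are uncertain where fragments could be split between copies.

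The other 9 lists tested did not pass by camera. In the gibberellin list, 1 of 5 tested members was lower, 0 were higher and 4 did not pass, and 2 were lower adjusted over the list alone (0 higher and 2 lower unadjusted, 0 and 1 by DESeq2). That gene was D8, which encodes a DELLA repressor, with a log2 fold change of −0.66 ± 0.11 (SE, edgeR adjusted p = 0.00305), and the list's camera adjusted p was 0.0585. It passed without sibling replicate 3, at 0.037, and without the filter on low counts, at 0.0379. In the cell cycle list, cycD2 (0.59) and kin15 (0.46) were higher and the histone gene H4C13 (−0.51) was lower among 48 tested members, and 45 did not pass. Adjusted over the list alone 2 were higher and 2 lower (4 higher and 11 lower unadjusted, 2 and 3 by DESeq2), and camera gave an adjusted p of 0.0595. It passed without sibling replicate 2, without mutant replicate 3 and without the filter, at adjusted p of 0.0128, 0.0484 and 0.0379.

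In the list of lateral organ identity and boundaries, 1 of 50 tested members was higher, 2 were lower and 47 did not pass, with 2 higher and 2 lower adjusted over the list alone (2 and 5 unadjusted, 2 and 2 by DESeq2; camera adjusted p = 0.276). Its symbol stems also took in grf1 and grf2, which are GF14 genes, and without these 1 was higher and 2 lower adjusted over the list alone. The members past the threshold were NAC61 (0.60), nam1 (−0.63), a NAC gene of organ boundaries, and the growth-regulating factor GRF12 (−0.54). Among 13 tested MADS-box genes, MADS34 was higher (0.81), MADS76 was lower (−0.89) and 11 did not pass, with 3 higher and 3 lower adjusted over the list alone (3 and 4 unadjusted, 1 and 2 by DESeq2; camera adjusted p = 0.743). The stems missed m21, whose symbol has the same form as the MADS-box members m24 and m31. It was higher (1.19 ± 0.29, SE, edgeR adjusted p = 0.0356), and the MADS-box list was not tested with it. Among the 27 tested members of the cytokinin list 0 were higher and 0 lower by edgeR, and 2 were higher adjusted over the list alone, with 3 higher and 3 lower unadjusted and 2 and 0 by DESeq2 (camera adjusted p = 0.548). Its stems took in the retinoblastoma-related genes rrb1 and rrb2. The 25 other members gave the same edgeR counts adjusted over all genes and over the list alone. The unadjusted and DESeq2 counts were not repeated without them. Of 31 tested bZIP and glutaredoxin genes, 0 were higher and 0 lower by edgeR, with 0 and 0 adjusted over the list alone, 1 and 2 unadjusted and 0 and 0 by DESeq2 (camera adjusted p = 0.743).

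In the joint list of brassinosteroid, abscisic acid, ethylene and jasmonate genes, 4 of 59 tested members were higher, 0 lower and 55 not past the threshold, with 5 higher adjusted over the list alone (5 higher and 3 lower unadjusted, 3 and 0 by DESeq2). They were the lipoxygenase genes lox6, lox1 and lox5, with log2 fold changes of 2.46 ± 0.53, 1.37 ± 0.27 and 0.87 ± 0.21, and the ethylene response factor EREB26 with 0.69 ± 0.12 (SE; edgeR adjusted p = 0.0161, 0.0443, 0.0415 and 0.00333). The list as a whole did not move one way: its median was −0.05, its mean 0.03 and its camera adjusted p 0.743. Without the filter on low counts the edgeR adjusted p of lox1 and lox5 was 0.195 and 0.297. lox5 also lost its call with the replicate number as a block (0.127) and by DESeq2 (0.172). lox6, lox1 and lox5 lost theirs in 4, 3 and 3 of the 6 cases of leaving out 1 library, with edgeR adjusted p up to 0.135, 0.207 and 0.287. In the vascular and cell wall list, the lipid transfer protein gene LTP3 was higher (0.63), CSLD1 was lower (−0.46) and 25 of 27 tested members did not pass, with 1 higher and 1 lower adjusted over the list alone (1 and 3 unadjusted, 1 and 1 by DESeq2; camera adjusted p = 0.789). In the heat shock and stress list, the chaperonin gene HSP60-1 was higher (0.52), the glutathione S-transferase genes GST3 (−1.74) and gst41 (−1.08) were lower and 32 of 35 tested members did not pass, with 2 higher and 2 lower adjusted over the list alone (7 and 4 unadjusted, 2 and 2 by DESeq2; camera adjusted p = 0.503).

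Lists for tissue that a dissected ear primordium should hold little of had too few tested members for a list test. For photosynthesis genes, 2 of 21 named members were tested, 0 passed the threshold by edgeR, adjusted over the list alone, unadjusted or by DESeq2, and the median log2 fold change was −0.30. Summed over the 21 members the level was 70.2 CPM ± 5.23 in siblings and 63.4 CPM ± 4.07 in mutants (SD, n = 3 each), but 90% and 91% of this was the single gene rcalm. Without rcalm and PSA2, the 2 tested members, it was 1.48 CPM ± 0.776 and 1.61 CPM ± 0.508 (SD, n = 3 each). For pollen, tapetum and seed genes 4 members were tested, and 1 was lower and 3 did not pass, with 1 lower adjusted over the list alone. That gene was the seed storage globulin gene glb1, with 5.92 CPM ± 1.96 and 1.90 CPM ± 0.662 (SD, n = 3 each; edgeR adjusted p = 0.037). The median over the 4 was 0.11. The sum over the 35 named members was 8.93 CPM ± 2.04 in siblings and 4.84 CPM ± 0.476 in mutants (SD, n = 3 each). Without glb1 it was 3.01 CPM ± 0.467 and 2.94 CPM ± 0.955 (SD, n = 3 each), so the difference came from glb1.

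**Figure D2:**
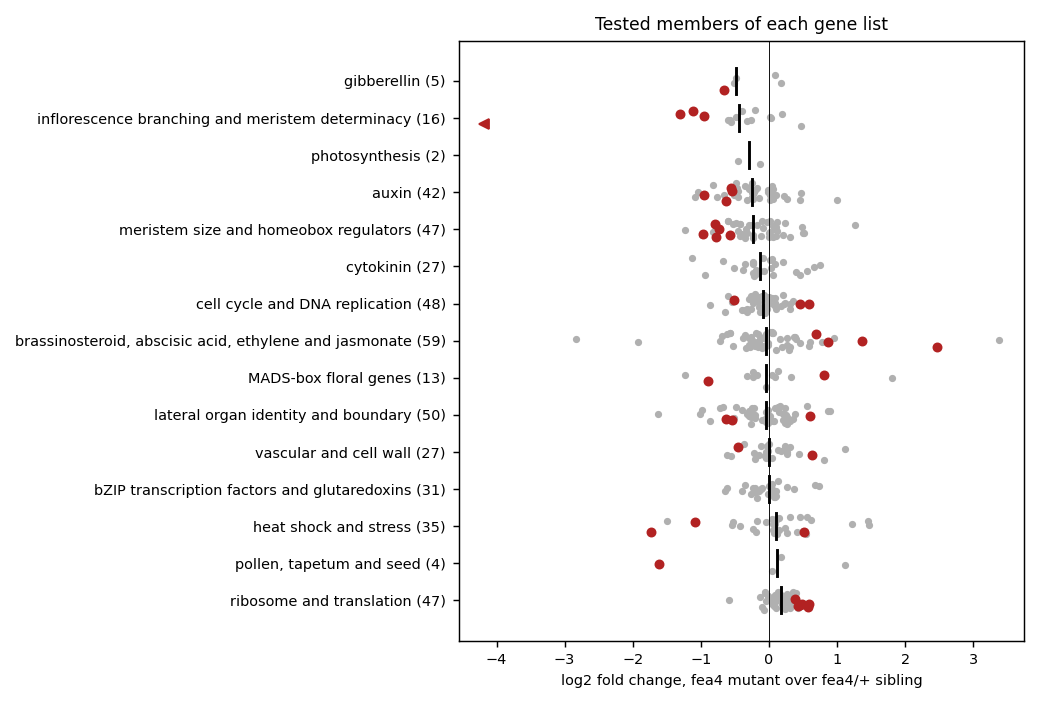
Log2 fold change of fea4 mutant over fea4/+ sibling ears (horizontal axis) for each tested member of the 15 gene lists (number tested in brackets); red points passed an edgeR adjusted p of 0.05, grey points did not, black bars are medians, and the triangle is bd1 at its bound of −4.18. The medians of the inflorescence branching, auxin and homeobox lists were −0.44, −0.25 and −0.23, and that of the ribosome list was 0.18.

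Among all changed genes with a gene name, the largest increase was in bx1, the first step of benzoxazinoid synthesis, with 1 fragment over the siblings and 180 over the mutants, a ratio of 182 (95% counting interval 32.2 to 7220; edgeR adjusted p = 0.00106). The next were lox6 and bx2, the second step of that pathway, at 1.41 CPM ± 0.185 in siblings and 5.83 CPM ± 0.279 in mutants (SD, n = 3 each), a log2 fold change of 2.04 ± 0.39 (SE, edgeR adjusted p = 0.00782). They were followed by hdz10 and by pdk1, which encodes pyruvate, orthophosphate dikinase (1.49 ± 0.21, SE, edgeR adjusted p = 0.000893). The alcohol dehydrogenase gene adh1 rose from 198 CPM ± 17.2 to 392 CPM ± 91.2 (SD, n = 3 each; log2 fold change 0.98 ± 0.13, SE, edgeR adjusted p = 0.000483) and the pyruvate decarboxylase gene pdc3 from 50.7 CPM ± 3.61 to 87.7 CPM ± 17.4 (SD, n = 3 each; edgeR adjusted p = 0.00303). Increases in m21 (1.19) and sdx1 (0.83), together with lox1, lox5 and MADS34, completed the 12 largest. After bd1, GST3, glb1 and ra1, the largest decreases were in PHS1 (−1.19), UGlcAE (−1.18), TAZ1 (−1.18), the polyamine oxidase gene MPAO (−1.16), ra3, the phosphoenolpyruvate carboxykinase gene pck2 (−1.08), gst41 and the cystatin gene cc3 (−1.0). Of the 49 named genes past the threshold, 15 kept their call whichever library was left out, among them ra3, BA1, ARF30, ocl4, D8, MPAO, gst41, bx1, adh1, pdc3, pdk1, EREB26, LTP3 and arpp2b. The other 34 lost it in at least 1 of the 6 cases, and glb1, PHS1 and aic1 lost it in all 6.

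The authors' deposited table held its own comparison of the same libraries, in which 455 genes passed an adjusted p of 0.05, 283 higher and 172 lower. Of these, 385 were also among the 512 genes, and all 385 had the same direction. Across 20615 genes, which are not independent replicates, Spearman's rho between the log2 fold changes in the authors' deposited table and those of edgeR was 0.998. Of the 49 named genes past the threshold by edgeR, 36 passed in the authors' deposited table and 13 did not. ra3 and ra1 had adjusted p of 1.79e-15 and 0.0283 there. Those that did not pass were bd1 (0.0527), ARF3 (0.063), aic1, lox1, lox5, GST3, MADS76, NAC61, CSLD1, UGlcAE, PHS1, cc3 and m21 (0.0545 to 0.404).

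The second data set asked where FEA4 was bound in the genome of developing tassels. FEA4 peaks were found on all 10 chromosomes, lay mainly towards the chromosome ends, and those in the highest score quintile of each list were largely shared with the other list. The authors called 5020 peaks in replicate 1 and 9644 in replicate 2, with median widths of 594 bp and 691 bp. By an overlap of at least 1 bp, 4116 replicate 1 peaks were shared (82.0%, Wilson 95% interval 80.9% to 83.0%), as were 4045 replicate 2 peaks (41.9%, 41% to 42.9%). Shuffling the replicate 2 peaks within their chromosomes gave a mean of 33.6 shared peaks and a maximum of 55 in 1000 draws, so the observed number was 122.5 times the chance mean (one-sided permutation p = 0.001, the smallest these draws can give). When the peaks were instead moved by 20 to 100 kb, which keeps their regional density, the chance mean was 68.0 and the observed number was 60.5 times it.

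The strongest shared peaks, ranked here by the sum of the authors' scores in the 2 replicates, were, in AGPv2 coordinates of replicate 1, at chromosome 2 from 3335286 to 3336948, chromosome 2 from 18791867 to 18792835, chromosome 10 from 147125758 to 147127206, chromosome 2 from 9098911 to 9100841 and chromosome 2 from 216615421 to 216616914. The authors' scores of the first were 890.0 in replicate 1 and 2447.2 in replicate 2. Genes and gene parts under these peaks were not analysed here, because gene positions in the AGPv2 build were not used here.

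Sharing rose with the authors' score within each list. In replicate 1, 63.7% of peaks in the lowest score quintile were shared, and 99.2% in the highest. In replicate 2 the shares were 14% and 86.7%. Across the 4116 shared pairs, which are not independent replicates, the scores had a Spearman's rho of 0.55, and summits lay a median of 49 bp apart. Requiring a reciprocal overlap of 0.5 left 3380 shared peaks, and summits within 150 bp left 3434. A score of at least 100 in both lists left 1811 and 4670 peaks, and 1616 replicate 1 peaks (89.2%) and 1598 replicate 2 peaks (34.2%) were then shared. The outer 25% at each end of the chromosomes held 69.8% of shared peaks (Wilson 95% interval 68.4% to 71.2%), against 50% for an even spread, with each chromosome taken to end at its last peak. Gene density along the chromosomes was not analysed here, so whether this excess is particular to FEA4 was not tested. Shared peaks also lay near each other, 1448 of them (35.2%) within 10 kb of another one, against a mean of 164.6 and a maximum of 222 in 200 uniform draws within chromosomes. These draws did not keep the excess towards the chromosome ends, which by itself brings peaks closer together.

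**Figure D3:**
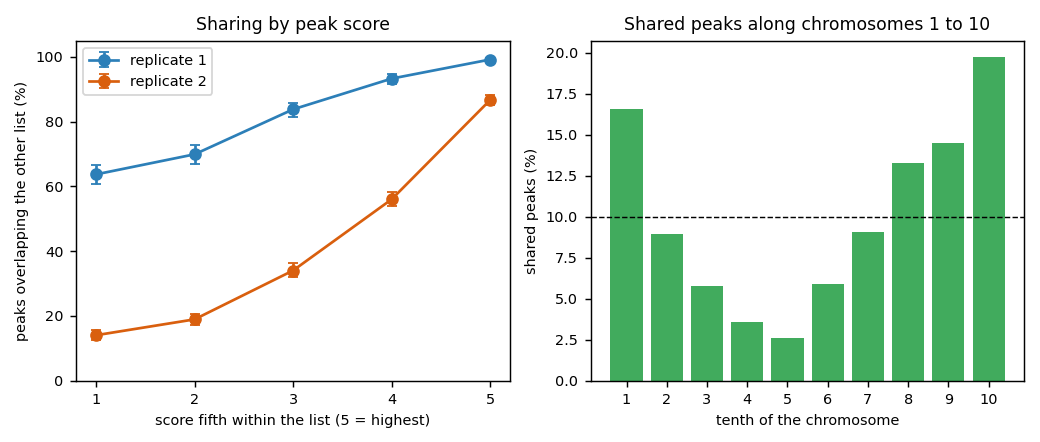
Left, percentage of FEA4 peaks of each replicate that overlapped a peak of the other (vertical axis, with Wilson 95% intervals) by quintile of peak score (horizontal axis); right, percentage of shared peaks in each decile of chromosome length, with the dashed line at an even 10%. The highest score quintile was shared at 99.2% and 86.7%, and the outermost deciles held 16.6% and 19.76% of the shared peaks, against 2.62% in the emptiest one.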

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

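The repeats with homonyms kept in, with hdz10 added, with the rrb and GF14 genes left out and with local shifts of peaks were chosen after the data were seen, as were the counts over other splits, and the remaining alternatives were planned. The number of changed genes was 512 and was 523 with RLE size factors, 922 without the filter on low counts, 893 by DESeq2, 186 by limma on log2(FPKM + 1), 455 in the authors' deposited table, 979 at a threshold of 0.1 and 117 with an absolute log2 fold change of at least 1. Of the 512 genes, 500 were also called by DESeq2, 506 without the filter and 164 by limma. Leaving out 1 library gave 156 to 811 genes: 182, 260 and 456 without sibling replicates 1, 2 and 3, and 229, 811 and 156 without mutant replicates 1, 2 and 3. Fewer samples tend to lower the count, but how much of each fall came from that was not tested. The cause of the rise without mutant replicate 2, the shallowest library, was not tested either. With the replicate number as a block, 719 genes were called (453 higher, 266 lower), 500 of them shared. Libraries with the same number did not deviate together (correlations of 0.006, −0.011 and −0.026), so the numbers were not taken as pairs, and the block changed no list call.

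With an estimated correlation 0 of the 13 lists passed camera, where 4 passed with the preset one. The camera adjusted p was 0.0718 for homeobox, 0.117 for inflorescence, 0.0718 for auxin and 0.257 for ribosome genes (unadjusted p 0.00852, 0.0271, 0.011 and 0.0791). The estimated correlation of the homeobox list, −0.008, lay below the preset 0.01, so a higher correlation did not cause its loss. What did was not tested. For these 4 lists limma's fry gave an adjusted p of 0.0101, 0.013, 0.0101 and 0.0462. It tests a list against no change and not against the other genes. The gibberellin list, which did not pass camera in the main fit, passed fry too, at an adjusted p of 0.0349. With the preset correlation the homeobox, inflorescence, auxin and ribosome lists passed camera in every other alternative run. Keeping homonyms gave 0.00113 for the homeobox list and 6.09e-07 for the inflorescence list, so removing them lowered both p-values, and adding hdz10 gave 0.00136 for the homeobox list. Leaving out the rrb and GF14 genes gave 0.743 for the cytokinin list and 0.169 for the lateral organ list. Gibberellin and cell cycle genes passed without the filter on low counts, both at 0.0379, and ranged from 0.037 to 0.171 and from 0.0128 to 0.247 on leaving out 1 library. The direction of the camera test turned on leaving out 1 library, always far from the threshold, for the brassinosteroid to jasmonate list (0.471 to 0.974, turned without sibling replicate 1, at 0.823, or 3), the bZIP list (0.579 to 0.974, turned without sibling replicate 3) and the cell wall list (0.594 to 0.994, turned without mutant replicate 1, at 0.949). The cause was not tested.

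Of the 49 named genes past the threshold, 18 to 42 passed on leaving out 1 library (24, 30 and 35 without sibling replicates 1, 2 and 3, and 30, 42 and 18 without mutant replicates 1, 2 and 3), and 0 of the 49 changed direction in any of these edgeR fits. The log2 fold change of FEA4 ranged from −0.15 to 0.15, and was −0.02 without sibling replicate 2 and −0.15 without mutant replicate 1. td1 passed without the filter and without mutant replicate 2 (edgeR adjusted p = 0.0329 and 0.033).

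At a score of at least 100, 1616 replicate 1 peaks were shared, since fewer peaks enter, and with equal numbers of best-scoring peaks 3281 were. The fold over chance was 122.5 with shuffles and 60.5 with local shifts, which keep regional density. A shared count without 1 ChIP replicate cannot be made, as sharing needs both. The alternatives for genes near peaks and for their overlap with changed genes were not run.

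Of the 10 ways to split the 6 libraries into groups of 3, the real one gave 512 genes by edgeR and the highest other gave 0 (unadjusted p under 0.05: 3337 in the real split, 389 to 1504 in the others; DESeq2: 893, against 0 to 140). For lists past the threshold with the preset correlation the real split gave 4. The 9 others gave 2, 1, 2, 0, 1, 1, 2, 1 and 1, so most of the other splits also called a list. The 10 splits cannot give a share under 0.05. Each of the 9 others put libraries of both genotypes in each group. A genotype difference would then widen the spread within groups and lower the calls, so their 0 genes by edgeR are no measure of chance.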

Other observations

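The anaerobic and benzoxazinoid gene groups below were drawn up after their values had been seen, so their counts describe these libraries and are no evidence for a group effect. The tests of the shallow library, of developmental stage, of other sugar breakdown genes, of the bx neighbours and of green tissue were also chosen after the results were seen, whereas the test of the inflorescence list with length and expression trends removed was set down beforehand. The same test of the anaerobic group was set down before it was run, but on a group whose values had been seen.

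Several genes of the anaerobic response were higher in the mutant ears. Of 11 tested genes that encode proteins made under low oxygen in maize, 5 were higher, 0 lower and 6 not past the edgeR threshold, and 9 were higher adjusted over the list alone. Besides adh1 and pdc3, the glyceraldehyde-3-phosphate dehydrogenase genes gpc4 and gpc3 had log2 fold changes of 0.70 ± 0.10 and 0.50 ± 0.10 (SE; edgeR adjusted p = 0.00141 and 0.0079), although these close copies can share fragments, and the enolase gene eno1 had 0.41 ± 0.10 (edgeR adjusted p = 0.0403). The haemoglobin gene Hb had 2.89 ± 0.79 (edgeR adjusted p = 0.0581) and the sucrose synthase gene sh1 0.36 ± 0.10 (edgeR adjusted p = 0.0595). Of 11 other sugar breakdown genes, 1 was higher, eno2 (0.38, edgeR adjusted p = 0.0406), 0 were lower and 10 did not pass, with 2 higher and 1 lower adjusted over the list alone.

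Of 7 tested benzoxazinoid genes, 4 were higher, 0 lower and 3 not past the threshold, and 6 were higher adjusted over the list alone. After bx1 and bx2, BX5 and BX3 had log2 fold changes of 0.67 ± 0.12 and 0.64 ± 0.14 (SE; edgeR adjusted p = 0.0033 and 0.0149), while BX4, bx8 and bx9 had 0.58, 0.14 and 1.01 (edgeR adjusted p = 0.0813, 0.823 and 0.102). In all, 8 changed genes had at most 3 fragments in each library of 1 genotype, 5 of them seen in the mutants and 3 in the siblings.

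The list of inflorescence regulators, of which 4 of 16 members passed, was lower by camera with the preset correlation only (adjusted p = 0.117 with an estimated one). At the preset correlation that lower level did not rest on the shallow library, since the list stayed lower without mutant replicate 2 (camera adjusted p = 5.68e-07). A trend of the test statistic with gene length or expression level did not take away the lower median. With that trend removed the median moved from −0.44 to −0.37. The list's adjusted p was then 3.12e-07 by limma's cameraPR, again with the preset correlation. With the trend in place the list did not pass at an estimated correlation, so this p-value cannot settle the matter. The trend explained 4.9% of the variance. Ears at an earlier stage may also hold less of these transcripts, and the MADS-box list did not settle this (camera adjusted p = 0.743). Whether each member of that list marks a later stage was not checked, and m21 was not in it. A batch that runs along with genotype was not tested and stays open, since the batch of each library is not given in the sources used here. Lower expression through loss of FEA4 was not tested either, as the overlap of FEA4 peaks with these genes was not run. Nor was a smaller share of the expressing cells in the pooled ears tested.

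For the higher level of the anaerobic genes, neither the length and expression trend nor a general rise in sugar breakdown was excluded. With the trend removed the median moved from 0.50 to 0.38 (cameraPR adjusted p = 3.32e-12, preset correlation). The median of the other sugar breakdown genes was 0.08 (exact permutation p = 0.000542, two-sided). These groups were chosen with their values known, which leaves both tests without weight. A candidate explanation is that the mutant ears, if bulkier than those of the siblings, held less oxygen. This was not tested, as these data hold no measure of bulk or oxygen, and a difference in handling of the pools stays open as well.

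The higher level of benzoxazinoid genes may come from a different haplotype at the bx cluster in the mutant plants, since the mutation was crossed into other inbred lines. Of 45 neighbouring genes other than bx genes, within 25 mapped genes on each side of bx1, 0 changed by edgeR (4 unadjusted and 0 by DESeq2; Clopper-Pearson 95% upper limit 7.87%, against 2.76% of all mapped genes), and 1 of 71 and 4 of 121 did within 50 and 100, so this stays open. The plants segregated in families, so a haplotype not linked to fea4 could occur in pools of both genotypes. Whether the bx cluster is linked to fea4 was not analysed here. Green leaf or husk tissue in the mutant pools would raise photosynthesis genes. Without rcalm and PSA2, the summed level of 19 such genes in the mutants was 1.08 times that in the siblings. The libraries overlapped, at 1.96, 1.84 and 1.03 CPM in the mutants and 0.733, 1.44 and 2.28 CPM in the siblings, and these sums rest on 12 to 48 fragments per library. A small share of green tissue therefore stays open, and young tissue that is not green was not tested.

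Around FEA4, 1 of 50, 7 of 100 and 9 of 200 neighbouring mapped genes changed within 25, 50 and 100 genes on each side (Fisher's exact p, two-sided: 1, 0.0207 and 0.127), unadjusted over the 6 windows tried here and around bx1. At an unadjusted edgeR threshold of 0.05, 11, 27 and 46 changed, against 3337 of all 20618 tested genes. By DESeq2 3, 11 and 17 did, against 893 of 18788. No test was run on these last counts. Over the whole gene order, 58 pairs of changed genes lay within 5 places of each other, against a chance mean of 52.2 (one-sided permutation p = 0.218).

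In the peak lists, 1 replicate 2 peak lay on the chloroplast sequence, and 2 and 3 peaks lay on unplaced sequence in replicates 1 and 2.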
